A study of Drosophila melanogaster with 90 samples.

How the data were processed

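The samples were whole virgin and mated females of 5 inbred lines, in 30 groups (25 crosses and 5 groups of virgins) planned with 3 libraries each. Per the labels' protocols, replicates came from separate bottles, the matings of all replicates were set up together, RNA was pooled from 5 to 10 females, and libraries were sequenced as single reads of 100 bases. Per the submitters' processing notes, FastQC, Trimmomatic, TopHat2 and HTSeq were used with the genome build dm3; no versions, annotation release, options or strand setting are given in the sources used here, so overlapping and antisense genes cannot be told apart with certainty. The deposited values are raw read counts per gene, whole numbers with no normalization. They cover 89 of the 90 labelled samples; replicate 2 of Ithaca x Zimbabwe has no column and was not analysed here.

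The table has 14522 gene rows under gene symbols. In 8 of them a number stands in place of the symbol, and these were left out. A reference annotation of another build (BDGP6) was used for names and exon lengths only: 14336 symbols (98.8%) matched 1 gene. CG8799 is given by its locus tag in the reference, where the table has a symbol with brackets. No coordinates are given, since the reference and the files differ in build. The smallest distance between replicates relative to Poisson counting error was 12.2 (chi-square per degree of freedom over 88 pairs within groups, genes with at least 10 counts). Over these genes as a set, differences between replicates, not counting error, set the precision. Genes with fewer counts are not covered by this value.

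Analyses used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by edgeR's filterByExpr over the 30 groups (12045 genes), library sizes were scaled by TMM (factors 0.740 to 1.10), and a quasi-likelihood model with 1 mean per group was fitted to all 89 libraries with robust estimation. The comparisons were contrasts of group means: mated minus virgin females, averaged over female lines and within each line; the difference of that contrast between lines; female line among virgins; male line averaged over female lines and within each; female line by male line; and same-line against different-line males. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and standard errors are the absolute log2 change divided by the square root of F. CPM values use TMM library sizes. The 27 gene lists were tested with limma's camera on log2 CPM (prior count 2) in the mean contrast, two-sided, with a preset correlation of 0.01 and again with an estimated one, adjusted over the lists. The lists were antimicrobial peptides, immune recognition and signalling, yolk proteins and uptake, eggshell, digestive serine proteases, carbohydrate digestion, lipid metabolism, seminal fluid proteins, ejaculatory duct and bulb, testis and sperm, female reproductive tract secreted proteases, heat shock and chaperones, odorant-binding proteins, cytochrome P450, glutathione S-transferases, juvenile hormone and ecdysone, neuropeptides, synapse and neuron, muscle sarcomere, cytosolic and mitochondrial ribosomal proteins, proteasome, circadian clock, DNA replication, female germline, fat body and hemocytes. Some genes stand in more than 1 list. Sums of male reproductive transcripts were compared as log2(CPM + 0.1) between mated and virgin libraries of a line by a two-sided exact permutation test, adjusted over 5 lines. The response score was compared between male lines with 100000 permutations within female lines, two-sided.

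The comparisons, lists, rule for named genes and a first set of alternatives were fixed before the data were examined. The rule names, for the mean contrast, the 8 largest rises and falls with a mean log2 CPM of at least 1 and the same sign in 5 lines, and up to 3 called members per list by smallest p; within each female line, the 3 largest called rises and falls with a mean log2 CPM of at least 1; for female line by mating, up to 12 genes by smallest p with that mean and a range of line changes of at least 1; for virgins, 10 by smallest p with that mean; for male line and female line by male line, all calls if 15 or fewer, otherwise 12 by smallest p; for male line within a female line, 3; and for same-line males, all calls if 10 or fewer. For the male tissue lists it names the 5 members with the highest mean CPM in mated libraries. Alternatives fixed in advance were DESeq2's size factors in edgeR, DESeq2's own test, no filter on low counts, CPM by total counts and a pseudocount of 1 for the sums, a block for the replicate number, leaving out each replicate number, leaving out each virgin library, and fits on the libraries of 1 female line or on mated libraries alone. Chosen after seeing the data were leaving out the 6 libraries with a testis sum above 10 CPM, leaving out those and libraries with more than 10% of other-line RNA (9 libraries; a further one was kept since its cross would have none left), a covariate for each library's slope of log2 expression on log2 gene length (genes with a mean log2 CPM above 3), both together, and leaving out the 6 and libraries with a slope below -0.2.

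Other-line RNA was estimated, after seeing the data, from genes expressed above 5 CPM in 1 other line and at least 8-fold lower in the female's own line, and at least 4-fold lower in the remaining lines, with the 8 genes of the female line by mating test and the male tissue lists left out, as the median share of the other line that their levels imply. Line levels are medians of mated libraries, so these genes were chosen on the same data. On counts simulated for the 12045 genes from the mean levels and library sizes measured, with 200 genes changed for each comparison tested, the test recovered 97.0% of 1.5-fold and 100% of 2-fold changes for mating in the mean of lines, with 3.08% of calls false. For male line in the mean of female lines it recovered 83.6% at 1.5-fold and 98.5% at 2-fold. For female line among virgins it recovered 7.46%, 71.6% and 90.9% at 1.5-, 2- and 3-fold, and for female line by male line, with 1 cross changed, 0%, 13.4% and 83.3%. The simulated genes were independent, with the same level in all lines and a spread set by their level alone. Changed genes had a mean log2 CPM above 1. No library held male or other-line RNA or a gene length slope, so these rates need not hold for the real libraries.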

Results

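RNA from whole female flies of 5 inbred Drosophila melanogaster lines (Beijing, Ithaca, Netherlands, Tasmania and Zimbabwe) was sequenced. Females of each line were mated with males of each line, which gives 25 crosses, or were kept as virgins. Mated females were frozen 5 to 6 h after mating began, and each library pooled 5 to 10 females. The labels plan 3 libraries for each of the 30 groups, from flies raised in separate bottles. The count table holds 89 of the 90 labelled libraries, 15 from virgin and 74 from mated females; Ithaca x Zimbabwe (the female line is named first) has 2 libraries. Total counts per library ranged from 4407704 to 38799730, and 12045 genes had enough counts to be tested. In Beijing females the totals were 6969673 to 38799730 in mated (n = 15) and 15522794 to 25950520 in virgin libraries (n = 3). In Ithaca females they were 4407704 to 30257647 (n = 14) and 11028958 to 13970275 (n = 3). A range widens with the number of libraries, so these values do not show that mated libraries varied more in depth.

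The first comparison asks which transcripts of females changed with mating, averaged over the 5 female lines (74 mated against 15 virgin libraries). The largest changes are given among genes with a mean log2 CPM of at least 1 and the same sign in 5 lines. The largest rises were in Send2, a serine protease of the sperm storage organs, with a log2 fold change of 4.31 ± 0.50 (SE; 19.8-fold, adjusted p = 6.89e-09), and in CG17234, a predicted serine protease, with 3.74 ± 0.47 (13.4-fold). Send2 averaged 22.5 ± 3.62 CPM (SD, n = 3) in Beijing virgins and 117 ± 39.7 (n = 15) after mating; in Netherlands females it went from 0.522 ± 0.379 (n = 3) to 18.6 ± 15.5 (n = 15). The related protease Send1 fell by 1.81 ± 0.20 on the log2 scale (adjusted p = 1.80e-09), so that these proteases did not move as a block. Rises above 2-fold were also measured in the cytochrome P450 gene Cyp4d21 (1.99 ± 0.26), the cuticle protein genes Pcp (1.72 ± 0.20) and Cpr47Ef (1.21 ± 0.14), CG14191 (1.57 ± 0.28), jhamt, which encodes a methyltransferase of juvenile hormone synthesis (1.57 ± 0.21), and the immune-induced gene Listericin (1.38 ± 0.17). After Send1, the largest falls were in PGRP-SC1b (-1.39 ± 0.18) and PGRP-SC1a (-1.05 ± 0.23), which encode peptidoglycan-degrading amidases, the noncoding RNA CR34335 (-1.10 ± 0.16), pirk, an inhibitor of the Imd immune pathway (-0.90 ± 0.11), the cuticle gene TwdlE (-0.85 ± 0.18), CG16775 (-0.78 ± 0.12) and the C-type lectin gene lectin-28C (-0.78 ± 0.17). PGRP-SC1a and PGRP-SC1b are near-identical copies, so their separate values are uncertain.

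**Figure D1:**
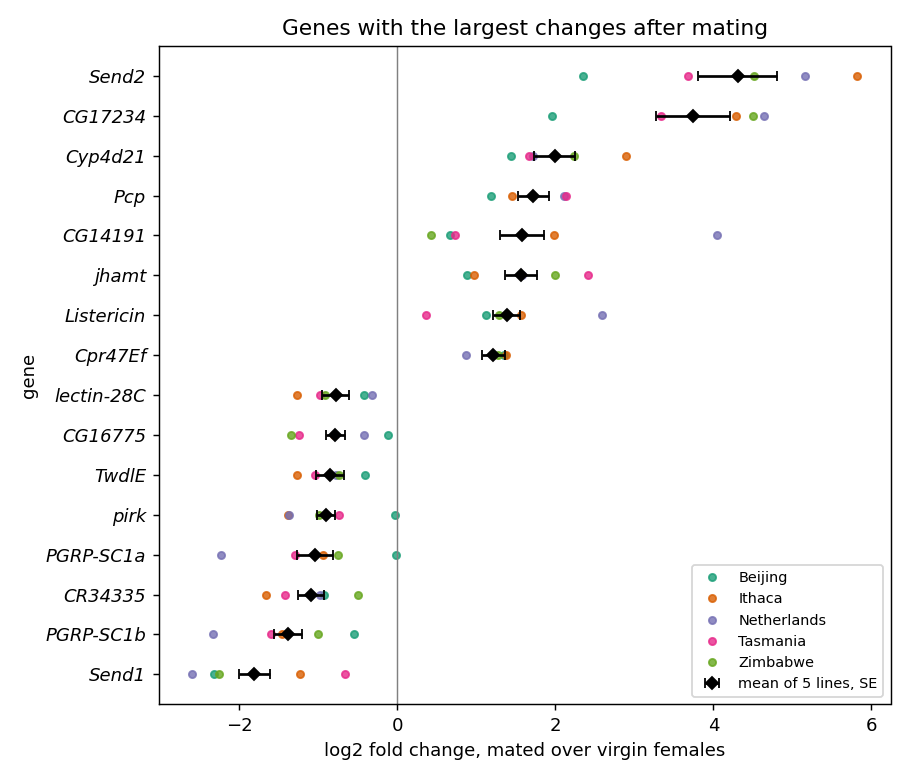
Log2 fold change of mated over virgin females (x axis) for the 8 largest rises and 8 largest falls named by the rule (y axis). Coloured points are the 5 female lines and diamonds are their means with SE; Send2 has the highest mean (4.31) and Send1 the lowest (-1.81), and each gene's 5 line values lie on 1 side of 0.

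In all, 678 of the 12045 genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 501 higher and 177 lower, and 39 of them changed at least 2-fold. Of the 678, 587 (86.6%) had a fitted change of the same sign in all 5 lines (17.4% of all genes tested), a share raised by choosing genes on the mean of the same lines. The count fell to between 241 and 404 when 1 replicate number was left out of all groups. It was 1555 with each library's slope of expression on gene length as a covariate, 844 higher and 711 lower, so the balance of rises and falls changed too. In the same edgeR test PGRP-SC1a, TwdlE and lectin-28C did not pass without replicate 3 (adjusted p = 0.113, 0.113 and 0.0513).

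Among female reproductive tract secreted proteases, 3 of 12 measured genes rose and 1 fell, with Send2, CG17234 and CG17239 (1.16 ± 0.24) higher and Send1 lower; adjusted over the list alone, 4 rose and 1 fell. As a group the list rose relative to other genes (camera with a preset correlation, adjusted p = 0.00344; adjusted p = 0.484 with an estimated correlation). Of 31 odorant-binding protein genes, which encode secreted carriers of small molecules, 5 rose and 0 fell, including Obp19b (0.72 ± 0.15), Obp49a (0.69 ± 0.15) and Obp69a (0.67 ± 0.17); 9 rose and 0 fell adjusted over the list alone. This list had the smallest group p (adjusted p = 4.90e-05; adjusted p = 0.658 with an estimated correlation). Of 13 heat shock and chaperone genes 4 rose, among them Hsp68 (0.78 ± 0.13), the Hsp90 gene Hsp83 (0.27 ± 0.07) and the mitochondrial chaperone gene Hsc70-5 (0.19 ± 0.05, lost without Ithaca virgin replicate 1, adjusted p = 0.0514). Adjusted over the list alone, 5 rose and 1 fell, and the list rose as a group (adjusted p = 0.0278; adjusted p = 0.579 with an estimated correlation; adjusted p = 0.101 and 0.0954 without replicates 1 and 3).

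No antimicrobial peptide gene passed among all genes (0 of 25), while 7 passed adjusted over the list alone, all higher. The list had a median log2 change of 0.60 in edgeR and 0.48 in the log2 CPM of the list test, and rose relative to other genes (adjusted p = 3.83e-04; adjusted p = 0.853 with an estimated correlation). The largest member values included AttC at 1.15 ± 0.42 (adjusted p = 0.0999) and IM23 at 1.16 ± 0.38 (adjusted p = 0.0535). The list's median log2 change was 2.03 in Netherlands females, 0.80 in Beijing, 0.37 in Zimbabwe, -0.05 in Ithaca and -0.18 in Tasmania, but 0 members differed between lines in their response to mating. Of 39 genes of immune recognition and signalling, 4 rose and 5 fell (5 and 5 adjusted over the list alone). The receptor gene PGRP-SA (0.58 ± 0.13) was among the 4, and pirk and the PGRP-SC1 genes among the 5; PGRP-SA lies outside the rule for named genes and was chosen after its values were seen. Of 14 hemocyte genes 1 fell, the phagocytosis receptor gene nimC1 (-0.31 ± 0.08, lost without Netherlands virgin replicate 1, adjusted p = 0.0695). Adjusted over the list alone 3 fell, and the list fell as a group (adjusted p = 0.0325; adjusted p = 0.801 with an estimated correlation). It did not pass without the 9 libraries that hold male or other-line RNA, described below (adjusted p = 0.195), without replicates 1 or 3 (0.0936 and 0.0537), or with the gene length slope as a covariate (0.106).

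Of 54 synapse and neuron genes 3 rose and 2 fell, also when adjusted over the list alone. The 3 were ple, which encodes tyrosine hydroxylase (0.69 ± 0.17), SPR, the sex peptide receptor gene (0.40 ± 0.10), and the sex-determination gene dsx (0.35 ± 0.07). The 2 lower genes, Oamb, an octopamine receptor gene (-0.34 ± 0.11), and Cam, the calmodulin gene (-0.19 ± 0.05), lie outside the rule for named genes and were chosen after their values were seen. The list as a whole fell relative to other genes (median -0.08 in the log2 CPM of the test; adjusted p = 0.0278; adjusted p = 0.982 with an estimated correlation). It did not pass without the same 9 libraries (adjusted p = 0.317), without replicates 1 or 2 (0.166 and 0.107), or with the gene length slope (0.155). DNA replication genes also fell as a group (adjusted p = 0.0181; adjusted p = 0.982 with an estimated correlation). They turned higher without replicate 2 (adjusted p = 0.509) and did not pass with the gene length slope as a covariate (adjusted p = 0.0717). In this list 2 of 23 were lower, Orc4 (-0.23 ± 0.06) and Orc6 (-0.21 ± 0.07), subunits of the origin recognition complex. Of 37 neuropeptide genes 1 fell, the insulin-like peptide gene Ilp7 (-0.77 ± 0.15), and the list did not pass (adjusted p = 0.432).

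Of 78 cytochrome P450 genes 10 rose and 4 fell (12 and 9 adjusted over the list alone). Cyp6a8 rose by 0.92 ± 0.16 and Cyp6g1 fell by 0.31 ± 0.07, and as a group the list did not pass (adjusted p = 0.958). Of 33 juvenile hormone and ecdysone genes 1 rose, jhamt (list adjusted p = 0.664). Of 26 lipid metabolism genes 2 rose and 2 fell (3 and 4 adjusted over the list alone; list adjusted p = 0.574), among them CG15828, which matched the lipid transfer gene Apoltp by an older symbol (0.57 ± 0.14), and CG12262, which matched Mcad, an enzyme of fatty acid oxidation (-0.21 ± 0.05). Of 20 carbohydrate digestion genes 1 rose and 2 fell (3 and 3 adjusted over the list alone; list adjusted p = 0.574): CG9468, a predicted mannosidase (0.81 ± 0.19), and the maltase genes Mal-A8 (-0.78 ± 0.21) and Mal-B1 (-0.62 ± 0.19). Of 10 fat body genes 2 rose, CG15828 and to, which encodes the takeout carrier protein (0.49 ± 0.13) and is also the 1 member of 9 circadian clock genes that rose, while desat1, a fatty acid desaturase gene, fell by 0.18 ± 0.06 (3 rose and 1 fell adjusted over the list alone; list adjusted p = 0.432 for fat body and 0.574 for the clock). Of 34 glutathione S-transferase genes 1 fell, GstZ2 (-0.41 ± 0.09; 2 rose and 2 fell adjusted over the list alone; list adjusted p = 0.878). A few other lists held 1 called gene: RpLP0-like (0.27 ± 0.08) of 92 in cytosolic ribosomal proteins, mRpS30 (0.15 ± 0.04) of 72 in mitochondrial ribosomal proteins and Ser8 (0.64 ± 0.19) of 29 in digestive serine proteases, with list adjusted p = 0.366, 0.431 and 0.432. Calls were lost when some virgin libraries were left out singly, for desat1 with 8 of 15, Mal-B1 with 7, Orc6 and RpLP0-like with 9 each, Ser8 with 5 and Mal-A8 with 1; the highest adjusted p were 0.180 (without Netherlands virgin replicate 1), 0.152 (Zimbabwe 1), 0.220 (Tasmania 2), 0.140 (Ithaca 1), 0.0720 (Zimbabwe 3) and 0.0513 (Tasmania 3).

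No member passed among 34 eggshell, 30 female germline, 4 yolk protein and uptake, 27 muscle sarcomere or 40 proteasome genes, and these lists did not pass as groups (adjusted p = 0.366, 0.432, 0.574, 0.574 and 0.712). The yolk protein gene Yp1 had a log2 change of 0.17 ± 0.15 and the eggshell gene Cp36 one of 0.28 ± 0.28. Median, mean and test differed in sign for cytochrome P450, immune recognition and signalling, juvenile hormone and ecdysone, lipid metabolism and proteasome. Altogether 10 of the 27 lists passed with the preset correlation, 7 of them described above, and 0 passed with an estimated correlation; 5 passed without the 9 libraries that hold male or other-line RNA.

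The remaining 3 lists that passed are of male reproductive tissue: seminal fluid proteins, testis and sperm, and ejaculatory duct and bulb, all higher in mated females (adjusted p = 0.00344, 0.0126 and 0.0278; with an estimated correlation, adjusted p = 0.982, 0.982 and 0.658). Only Sfp84E passed singly among 52 seminal fluid genes (1.79 ± 0.49, at a mean of 0.0783 CPM in virgins and 0.284 CPM in mated females), and 0 of 26 testis genes did. Summed per library, testis transcripts were at 1.51 to 5.80 CPM in the 15 virgin libraries and at a median of 3.83 CPM in the 74 mated ones. They exceeded 10 CPM in 6 mated libraries: Ithaca x Zimbabwe replicate 1 (1744 CPM), Netherlands x Beijing replicate 2 (1644), Ithaca x Ithaca replicate 3 (387), Ithaca x Tasmania replicate 3 (86.5), Beijing x Zimbabwe replicate 1 (47.3) and Ithaca x Netherlands replicate 1 (20.3). The other 83 libraries reached at most 7.21 CPM. In Ithaca x Zimbabwe replicate 1 the highest genes included the testis aminopeptidase S-Lap1 at 261 CPM, loopin-1 at 211 CPM and the seminal protein Acp36DE at 228 CPM. In a two-sided exact permutation test of mated against virgin libraries the seminal fluid sum passed in 0 of 5 lines (adjusted p = 0.722 in each) and so did the testis sum (adjusted p = 0.516 in each). Outside the 6 libraries the seminal fluid sum reached at most 12.0 CPM. Whether the list tests rest on the 6 was not tested other than by leaving out these 6 libraries. Without them the seminal and testis lists had adjusted p = 0.593 and 0.967, which follows from how the 6 were chosen. The ejaculatory duct and bulb list had adjusted p = 0.0899 without the 6, 0.117 without the 9 and 0.0742 without replicate 1.

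**Figure D2:**
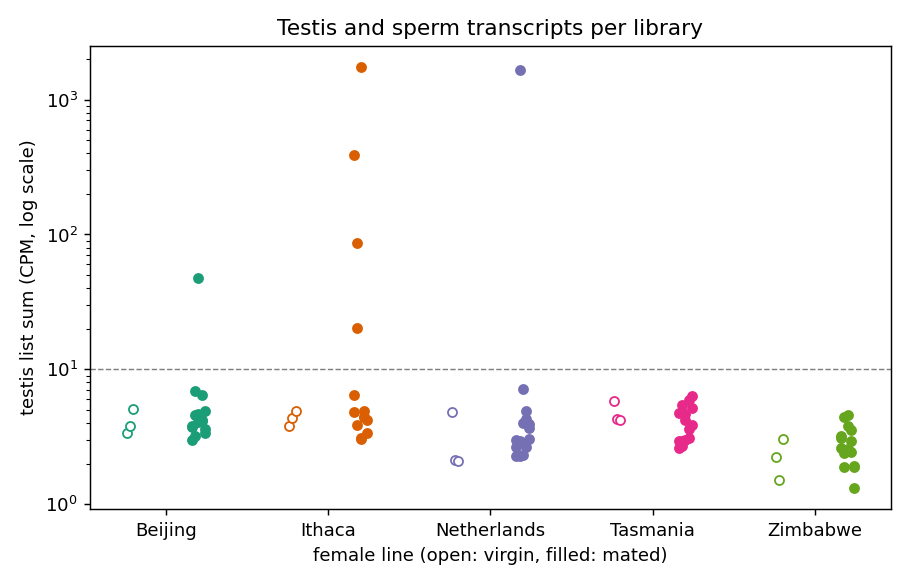
Sum of testis and sperm transcripts per library in CPM (y axis, log scale) by female line (x axis), with open points for virgin and filled points for mated libraries and a dashed line at 10 CPM. Of the 74 mated libraries 6 lie above the line, up to 1744 CPM, and the virgin libraries lie between 1.51 and 5.80 CPM.

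The ejaculatory duct and bulb sum rose in mated females of all 5 lines (two-sided exact permutation test, adjusted p from 0.0123 in Zimbabwe to 0.0485 in Ithaca). Zimbabwe females went from 260 ± 28.7 CPM (SD, n = 3) to 457 ± 89.3 (n = 15), and Tasmania females from 421 ± 57.3 to 629 ± 150. In virgins nearly all of it was PebIII, which averaged 337 CPM in virgin and 537 CPM in mated libraries (log2 change 0.67 ± 0.11, adjusted p = 2.46e-05), so this member is not restricted to males. With virgin replicate 1, 2 or 3 left out and all mated libraries kept, the sum passed in 0, 2 and 0 lines. Each line then had 2 virgin libraries.

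Within single female lines, fewer genes passed, each test resting on 3 virgin libraries. Send1 was the only gene called in 3 lines, with log2 changes of -2.31 ± 0.45 in Beijing, -2.60 ± 0.41 in Netherlands and -2.25 ± 0.43 in Zimbabwe; no gene was called in more. In Ithaca females, 12 genes rose, among them Send2 (5.82 ± 1.27), the homeotic gene Scr (1.59 ± 0.33) and CG7695 (1.34 ± 0.26), and 9 fell, among them the digestive protease gene Jon66Ci (-3.03 ± 0.56), CR34335 (-1.66 ± 0.36) and pirk (-1.38 ± 0.24). In Netherlands females, 11 rose, with CG14191 (4.04 ± 0.73), Listericin (2.59 ± 0.43) and Pcp (2.11 ± 0.46), and 4 fell, with Send1, PGRP-SC1b (-2.33 ± 0.37) and PGRP-SC1a (-2.23 ± 0.50). Zimbabwe females had 3 rises, CG5527 (1.00 ± 0.19), the small heat shock gene l(2)efl (0.95 ± 0.20) and CG3071 (0.47 ± 0.10), and 7 falls, among them CG5550 (-1.98 ± 0.44) and CG15126 (-1.51 ± 0.29). In Beijing females 0 rose and 3 fell, including Send1 and CG8799 (-1.33 ± 0.27). In Tasmania females 39 rose, among them jhamt (2.41 ± 0.46), CG30272 (2.31 ± 0.56) and Pcp (2.14 ± 0.42), and 60 fell, among them CG11313 (-4.68 ± 0.70), Cyp12d1-d (-4.48 ± 0.78) and the receptor gene mthl8 (-4.28 ± 0.49). Cyp12d1-d has a near-identical copy, so its value is uncertain.

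Of 26 calls of named genes within single lines, 2 held with each virgin library left out in turn (Listericin and Send1 in Netherlands). The counts without virgin replicate 1, 2 or 3 were 1, 0 and 8 in Beijing (3 with all), 9, 6 and 0 in Ithaca (21 with all), 92, 6 and 6 in Netherlands (15 with all) and 41, 53 and 2 in Tasmania (99 with all). In Zimbabwe (10 with all) they were 3, 1 and 14. A change called in 1 line and not in another is not shown to differ between them; that is the test of the next comparison.

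The female line by mating comparison asks which genes responded to mating differently in different lines, and 8 genes passed. For 7 of them the line that stood apart was Tasmania, where mated females had less than virgins: mthl8 (adjusted p = 7.38e-06), the protease gene Jon65Aii, GAPsec, CG7966, CG4998, CG32718 and CG11313. In Tasmania virgins, mthl8 was at 0.287, 0.0753 and 3.41 CPM in replicates 1 to 3 and at 0.0847 ± 0.0995 CPM (SD, n = 15) after mating; GAPsec was at 0.716, 0.376 and 5.89 CPM and at 0.524 ± 0.278 CPM after mating. CG4998 differed from the others in being highest in replicate 1 (3.01 CPM, against 0.978 and 1.43), and did not pass without it (adjusted p = 0.375); its Tasmania change was -2.10 ± 0.35 without replicate 3, where mthl8 had -1.36 ± 0.78. In Zimbabwe virgins mthl8 and GAPsec were at 16.2 to 20.4 and 25.1 to 30.9 CPM. The last gene, CG8799, had log2 changes of -1.33 ± 0.27 in Beijing and 0.81 ± 0.30 in Tasmania females. Beijing virgins held it at 4.46, 5.67 and 1.04 CPM and mated Beijing females at 1.60 ± 0.895 CPM (SD, n = 15), and it did not pass without Beijing virgin replicate 1 or 2 (adjusted p = 0.266 and 0.695). Without Tasmania virgin replicate 3, 0 genes passed (edgeR; 14 in DESeq2 with all libraries, and 414 at an unadjusted p under 0.05 in edgeR with all libraries); without Netherlands virgin replicate 1, 13 passed. Over 5 genes specific to Zimbabwe females, Tasmania virgin replicate 3 held an implied 21.1% of Zimbabwe RNA, and over genes silent in mated Tasmania females 8.94% of RNA of another line.

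**Figure D3:**
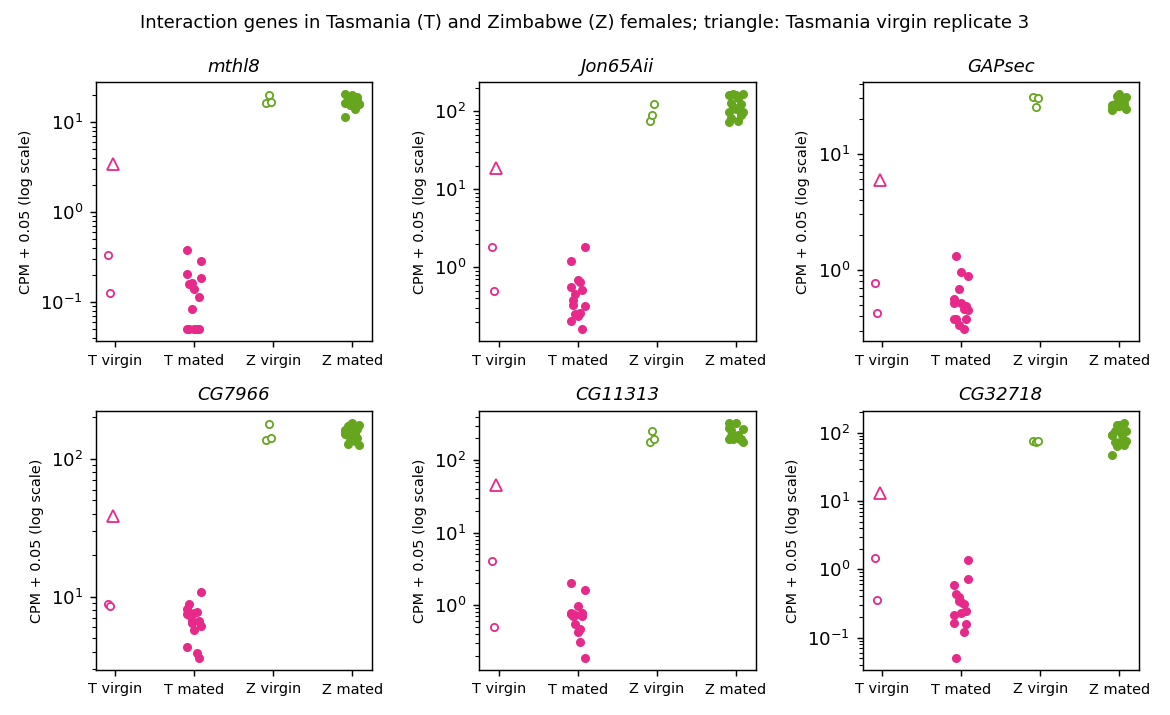
CPM plus 0.05 (y axis, log scale) of 6 of the 8 genes of the female line by mating comparison in virgin (open) and mated (filled) females of Tasmania and Zimbabwe (x axis). The triangle marks Tasmania virgin replicate 3, which for mthl8 was at 3.41 CPM beside 0.287 and 0.0753 CPM in the other virgin replicates.

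Whether lines responded alike was described across genes, which are not independent replicates. The log2 changes of 2 lines had a median Pearson r of 0.123 over the 10 pairs of lines (0.0307 to 0.468; Spearman's rho 0.195, 0.0634 to 0.378) across all genes tested. The highest of these, 0.468 for Ithaca and Netherlands, was 0.0570 without the 6 libraries of high testis sums and 0.0886 without the 9. The median r of the response similarity between female lines was then 0.184 and 0.188, and it was 0.0808 and 0.0673 without replicates 1 and 2. Across the 678 genes called in the mean, r was 0.705 (0.637 to 0.810), a value raised by the choice of genes. With genes chosen from the other 4 lines instead, the response score of the line left out, the mean log2 CPM of risen genes minus that of fallen ones relative to its virgins, was above 0 in each line. It ranged from 0.46 ± 0.08 in Beijing (SD, n = 15) to 0.78 ± 0.16 in Ithaca (n = 14; two-sided exact permutation test of mated against virgin libraries, adjusted p = 0.00147 in each line, close to the smallest the test can give). Between 86.4% (Tasmania) and 93.7% (Beijing) of those genes kept the sign.

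Virgin females of the 5 lines differed in 3308 genes (15 libraries). The gene with the smallest p was CR44101, at 16.0 ± 4.57 CPM in Beijing virgins (SD, n = 3) and 0.0744 ± 0.0658 in Zimbabwe virgins (adjusted p = 2.92e-24). Cyp6w1, a cytochrome P450 gene, was at 2881 ± 409 CPM in Ithaca and 96.5 ± 14.1 in Zimbabwe virgins. Brf, a subunit of a transcription factor of RNA polymerase III, was at 107 ± 16.1 CPM in Zimbabwe and at 27.1 to 32.0 CPM in the others. Single lines also stood apart for CG34411 (73.2 ± 19.1 CPM in Netherlands, at most 5.44 elsewhere), CG10154 (20.7 ± 6.35 CPM in Netherlands, at most 0.275 elsewhere) and CG14174 (44.6 ± 15.5 CPM in Tasmania, at most 8.78 elsewhere). By list, 60 of 78 cytochrome P450 genes differed (64 adjusted over the list alone), as did 24 of 29 digestive serine proteases (26), 24 of 39 immune recognition and signalling genes (25), 15 of 25 antimicrobial peptide genes (20), 20 of 34 glutathione S-transferases (23) and 19 of 34 eggshell genes (29), against 27.5% of all genes. The count was 1632 without replicate 3 and 5991 with the gene length slope as a covariate.

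The male comparisons ask whether the response of females depended on the line of the mate. Averaged over female lines, 1 gene passed, CG18095 (adjusted p = 0.00558). It was at 2.88 ± 1.13 CPM (SD, n = 2) in Ithaca x Zimbabwe and at 0.0526 to 0.221 CPM in the other crosses of Ithaca females. Crosses of Zimbabwe females had it at 11.1 to 13.8 CPM. Both Ithaca x Zimbabwe libraries held an implied share of Zimbabwe RNA (19.9% and 20.04%). An effect of male line on this gene therefore cannot be told apart from RNA of another line. DESeq2 called 9 genes, and leaving out replicate 1, 2 or 3 left 0. The female line by male line test called 425 genes, among them 18 of 52 seminal fluid genes (28 adjusted over the list alone), 13 of 26 testis genes (19), 11 of 25 antimicrobial peptide genes (17) and 4 of 39 immune recognition and signalling genes (4). Without the 6 libraries of high testis sums it called 18 genes. Without replicate 1 or replicate 2 it called 1, with 11 of the 12 named genes lost in each. CG7131, CG31029 and CG9129 were highest in the 2 libraries with the highest testis sums, at 35.9, 49.9 and 27.2 CPM in Ithaca x Zimbabwe replicate 1 and 38.0, 44.4 and 27.2 CPM in Netherlands x Beijing replicate 2, and had adjusted p = 1 without the 6.

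Within female lines, male line was called for 962 genes in Ithaca and 1355 in Netherlands, but for 21 and 39 without the 6 libraries, and for 23 and 7 without the 9 libraries that hold male or other-line RNA. In Ithaca these genes included 33 of 52 seminal fluid and 21 of 26 testis genes, and in Netherlands 36 and 25 (49 and 26, and 47 and 26, adjusted over the list alone). The genes of smallest p in Ithaca were CG18095, the noncoding RNA pncr009:3L and mthl8, each highest in Ithaca x Zimbabwe: pncr009:3L at 5.53 ± 4.91 CPM (n = 2) and mthl8 at 3.54 ± 1.78 CPM (n = 2), against at most 0.472 and 0.277 CPM in the other Ithaca crosses. In crosses of Zimbabwe females pncr009:3L was at 40.0 to 49.0 CPM, and mthl8 averaged 17.3 CPM. Both Ithaca x Zimbabwe libraries held an implied share of Zimbabwe RNA, 19.9% and 20.04% over 7 genes specific to Zimbabwe females. In Netherlands the lysozyme genes LysD and LysC, near-identical copies whose values are uncertain, reached 180 and 186 CPM in Netherlands x Ithaca replicate 2 and at most 1.83 and 1.10 CPM in the crosses with other males. That library held an implied 55.4% of Ithaca RNA. The third Netherlands gene, scpr-A, was at 44.7 CPM in Netherlands x Beijing replicate 2. Without replicate 2 male line called 0 genes in Netherlands females.

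In Tasmania females 25 genes differed by male line, including 6 of 25 antimicrobial peptide genes (11 adjusted over the list alone) and 4 of 39 immune recognition and signalling genes (12). The complement-like gene Tep1 was at 25.0 ± 30.1 CPM (SD, n = 3) with Zimbabwe and 8.18 ± 8.21 with Tasmania males, against at most 0.284 with others. The defensin gene Def was at 86.5 ± 100 and 40.3 ± 35.0 CPM, against at most 8.27. The serpin gene Spn28Dc was at 56.2 ± 45.1 and 110 ± 148 CPM, against at most 19.4. In both crosses the highest value of each of these genes was in replicate 1 (Def at 200 and 78.4 CPM), and replicate 1 carries the calls. In all, 0 genes passed without it, and 4 without replicate 2. In Beijing females 5 genes passed, and 0 without replicate 1. Of 25 antimicrobial peptide genes 0 passed, but 19 did adjusted over the list alone. The 5 included the immune-induced gene edin and CG34136, at 351 and 50.5 CPM in Beijing x Ithaca replicate 1 and at most 12.5 and 4.63 CPM with other males, and CG6614 (adjusted p = 0.995 without the 6 libraries). In Zimbabwe females edgeR called 0 genes (135 at an unadjusted p under 0.05; DESeq2 called 4). With the spread estimated from the mated libraries of the same female line alone, 0 genes passed in Beijing, Ithaca, Netherlands or Tasmania females.

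Females mated within their line were compared with those mated to another line (5 against 20 crosses). In edgeR 0 genes passed, with 74 at an unadjusted p under 0.05, and DESeq2 called 7. The strength of the whole response was compared between male lines by the response score of the 74 mated libraries, centred by female line. Mean scores were 0.04 ± 0.11 with Netherlands males (SD, n = 15), 0.03 ± 0.15 with Tasmania, 0.01 ± 0.12 with Ithaca, 0.01 ± 0.14 with Beijing and -0.10 ± 0.18 with Zimbabwe males (n = 14), which did not pass a permutation test within female lines (p = 0.0830). For this response score, male line passed without replicate 1 (permutation p = 0.0154) and without the 6 libraries (permutation p = 0.0384).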

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

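The test of a response particular to Tasmania females, below, was chosen only after the result was seen. The 8 genes whose response to mating differed between female lines stand out because the difference itself passed the interaction test of edgeR's quasi-likelihood model. In 6 of the 7 genes lower in mated Tasmania females the fall was smaller by over 2 SE without Tasmania virgin replicate 3 (mthl8 -4.28 ± 0.49 with it and -1.36 ± 0.78 without it; GAPsec -2.31 ± 0.27 and -0.10 ± 0.26), so a smaller response of Tasmania females cannot be told apart from none with the 2 virgin libraries left. RNA of another line in that library is a candidate explanation for these 6: over 5 genes silent in mated Tasmania females, with the 8 genes left out, it held 8.94% of RNA of another line, above the highest mated Tasmania library (4.72%). It leaves 2 genes open: CG4998, whose fall was -1.94 ± 0.30 with that library and -2.10 ± 0.35 without it, and CG8799, which had the largest change in Beijing females. For CG8799, RNA of another line in Beijing virgins was not tested. Over genes specific to Netherlands females, a measure chosen after seeing the data, Beijing virgin replicates 1 to 3 held an implied 8.99%, 4.1% and -1.03% of Netherlands RNA. Netherlands virgins held CG8799 at 24.4 to 38.0 CPM. A mated Beijing library had a similar share, 8.60% in Beijing x Tasmania replicate 3. Other groupings did not exclude chance for this count: 9 of 24 splits of mated and virgin labels within lines, the real one included, gave 8 genes or more, up to 3357, which points to a structure of the samples beyond mating.

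Table rows with a number in place of a gene symbol took 0.122% of all counts (0.0444% to 0.263% per library) and stand out as signal outside the genes analysed; which genes they hold is not known.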

How the results depend on the processing

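Alternatives that leave out the 6 or 9 libraries, or use the gene length slope, were chosen only after seeing the data; where fewer libraries or virgins remained, that is part of the change, and otherwise the cause was not tested. Over the alternatives, named genes kept the call, and the direction where the test has one, in 2073 of their values. They lost the call in 344, with 0 reversed. The tests of female line by mating, virgins, male line and female line by male line have no direction, so their values could not reverse. Of 44 named for the mean effect of mating, 18 kept the call in every alternative. Among the 16 largest rises and falls under the naming rule, 13 did. The 678 genes of the mean were all called with DESeq2 (850) and with the replicate block (856). List tests were alike in 223 values, lost in 29, gained in 10 and reversed in 8; a turn of direction counts as reversed only where the list passed in either fit, and as alike otherwise.

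Leaving out each replicate number gave 241 to 404 genes for the mean effect of mating and 0 to 7 for female line by mating. Mating within lines gave 0 to 1 for Beijing, 0 to 9 for Ithaca, 1 to 71 for Netherlands, 3 to 52 for Tasmania and 0 to 19 for Zimbabwe. The counts were 1632 to 2431 for virgins, 0 for male line in the mean and 1 to 251 for female line by male line. Male line within lines gave 0 to 13 in Beijing, 5 to 1060 in Ithaca, 0 to 888 in Netherlands and 0 to 14 in Tasmania females. With only the virgin libraries of a number left out, the ejaculatory duct and bulb sum passed in 0 to 2 lines. The range of the response score, male line, was 0.14 with all libraries, 0.190 without replicate 1, where it passed (permutation p = 0.0154), and 0.106 without replicate 2. Leaving out 1 virgin library gave 503 to 854 genes for the mean effect of mating (854 without Netherlands virgin replicate 1), 2876 to 3985 for virgins, 0 to 13 genes for female line by mating, 0 to 8 in Beijing, 0 to 9 in Ithaca, 6 to 92 in Netherlands, 2 to 53 in Tasmania and 1 to 14 in Zimbabwe.

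With DESeq2 the counts were 14 for female line by mating, 10 in Beijing, 101 in Ithaca, 58 in Netherlands, 185 in Tasmania, 70 in Zimbabwe, 9 for male line in the mean, 7 for same-line against different-line males, and for male line 26 in Beijing, 352 in Ithaca, 558 in Netherlands and 4 in Zimbabwe females. With libraries of the same female line alone mating called 38 in Ithaca, 3 in Netherlands, 4 in Tasmania and 1 in Zimbabwe, and male line 0 in Beijing, Ithaca, Netherlands and Tasmania; with mated libraries alone female line by male line called 185.

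The labels give the replicate numbers no shared source, and deviations of virgin and mated libraries with the same number had a correlation above 0.1 in 6 of 15 pairs (-0.294 to 0.350), so the numbers were not taken as pairs. Single libraries of the same number had a mean correlation of 0.143 within female lines and 0.0781 across them. Other numbers within female lines had -0.0698, and other numbers across lines were not measured. These correlations are at most a hint of a shared source and do not settle it. Slopes of expression on gene length also differed between numbers. The steepest were in replicate 2 of Netherlands x Ithaca (-0.690), Beijing x Ithaca (-0.582) and Beijing x Netherlands (-0.466). Replicate 1 reached -0.337 (Tasmania x Beijing) and replicate 3 reached -0.195 (Beijing x Beijing). Replicate 2 also held slopes up to 0.1145 (Zimbabwe x Zimbabwe). A dependence of the slope on the number was not tested. With the replicate block the counts were 5 in Beijing, 45 in Ithaca, 166 in Tasmania, 18 in Zimbabwe and 2 for male line in the mean, and the response score, male line, passed at the same range of 0.14 (permutation p = 0.0189); the block changed no other count by over 1.5 times.

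With the length slope as a covariate the counts were 1555 for the mean effect of mating, 5 in Beijing, 131 in Ithaca, 475 in Tasmania, 64 in Zimbabwe, 5991 for virgins and 3 for male line in the mean. Without the 6 libraries and with the slope they were 1640, 5, 137, 519, 74, 6233 and 2, with 11 for female line by male line, 28 and 35 for male line in Ithaca and Netherlands, and 6 lists. Without the 6 and libraries of steep slope they were 14 for female line by mating, 77 in Ithaca, 177 in Tasmania, 47 in Zimbabwe, 2 for male line in the mean, 14 for female line by male line, and 17, 28 and 1 for male line in Beijing, Ithaca and Netherlands. Without the 6 alone they were 17 in Zimbabwe, 2 for male line in the mean, 18 for female line by male line, and 2, 21 and 39 for male line in Beijing, Ithaca and Netherlands; the score range was 0.176 and passed (permutation p = 0.0384). Without the 9 they were 0 for female line by mating, 35 in Ithaca, 8 in Tasmania, 19 in Zimbabwe, 3 for male line in the mean, 17 for female line by male line, 17, 23 and 7 for male line in Beijing, Ithaca and Netherlands, and 5 lists.

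With an estimated correlation 0 lists passed. The direction turned for DNA replication without replicate 2 (adjusted p = 0.509; 2.02e-04 without replicate 3), digestive serine proteases without replicate 2 (0.0237; 0.00580 and 0.179 the other way without replicates 1 and 3), muscle sarcomere without replicate 3 (6.59e-05; 0.0483 the other way without replicate 2), seminal fluid proteins (0.593 without the 6, 0.591 with the slope too, 0.522 without the 9) and testis and sperm (0.967 and 0.912 without the 6 and 9). For the seminal and testis lists this follows from how the 6 were chosen.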

Other observations

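The test of RNA passed at each mating was chosen only after the result was seen, and so were the shares over genes specific to 1 line. The other tests in this part were set before, though those without 6 libraries use a choice of libraries made after seeing the data. Transcripts of male reproductive organs stood far above virgin levels in 6 of 74 mated libraries. RNA passed to females at each mating does not account for them, since the median testis sum of mated libraries was 3.83 CPM, within the range of virgins (1.51 to 5.80). Male flies or male tissue in the pool were tested over genes silent in the female line. The mate's line had the largest share in 2 of the 5 libraries with a mate of another line. By the bound set in advance, 2 or fewer counts against this explanation. It is left open here for a reason that was not part of that bound, that a small share may not be seen. In 3 of these 5, 1 of the 2 included, the share scaled from the testis sum of Ithaca x Zimbabwe replicate 1 would be at most 0.987%. That scaling takes the 19.9% of Zimbabwe RNA in replicate 1 as male RNA. Replicate 3 of the same cross held 20.04% with a testis sum of 4.47 CPM, within the range of virgins. Whether the shares of these 3 were too small to see is therefore uncertain, and the test does not decide. Over genes specific to 1 line the mate's line was largest in the 2 libraries outside these 3, at 19.9% and 17.1%. Over silent genes, however, Netherlands x Beijing replicate 2 held most from Zimbabwe (22.8%).

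Libraries also differed in a gradient of expression on gene length (slope from -0.690 to 0.163). Mating does not account for it: 0 of 5 female lines had a slope that differed between mated and virgin libraries (two-sided exact permutation test, adjusted p = 0.908 in each). Sequencing depth may contribute: slope and log2 total counts had a Pearson r of 0.301 over 89 libraries (permutation p = 0.00478; Spearman's rho 0.3004, permutation p = 0.00447), just past the bound of 0.3 set in advance. Without the 2 libraries farthest from the median depth r was 0.328, and within female lines it ranged from 0.0866 to 0.663. RNA quality stays open, since no measure of it is given. So does a source shared by libraries of the same replicate number, which was not tested for the slope.

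The same libraries were split into groups of the same sizes within female lines (23 splits drawn at random and the real one). For female line among virgins, the virgin libraries were split across lines instead. Chance was counted as excluded where only the real split of the 24 called as many genes. That is the smallest share the test can give, and it was not adjusted over the comparisons. This held for the mean effect of mating, with 678 genes against at most 69 in other splits (1 of 24 as large). The same holds for female line among virgins, with 3308 against at most 1737 (1 of 24). Mating in Tasmania females also exceeded all other splits, with 99 against at most 31 (1 of 24). That count was 2 without Tasmania virgin replicate 3, which held an implied 21.1% of Zimbabwe RNA. It was 8 without the 9 libraries and 4 with the libraries of this line alone, so the 99 are not read as an effect of mating. Chance cannot be excluded for mating in Zimbabwe (10 genes, 2 splits as large, highest other 24), Beijing (3 genes, 6 splits, 1003), Ithaca (21 genes, 5 splits, 1632) or Netherlands females (15 genes, 8 splits, 5149). For male line it could be excluded in no comparison with all libraries: male line in the mean (1 gene, 12 splits, highest other 117), female line by male line (425 genes, 4 splits, 1585), same-line against different-line males (0 genes, 24 splits, 236), and male line in Beijing (5 genes, 15 splits, 29), Ithaca (962 genes, 4 splits, 1344), Netherlands (1355 genes, 14 splits, 5579), Tasmania (25 genes, 11 splits, 120) and Zimbabwe females (0 genes, 24 splits, 5). Splits that called several times the real count point to a structure of the samples, such as single libraries that stand apart.

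Without the 6 libraries, male line in Ithaca females called 21 genes against at most 19 in other splits (1 of 24). This is the smallest share the test can give, in 1 of 8 comparisons, and 0 genes passed with the mated libraries of this line alone, so it is not read as an effect of male line. The 1 library left with Zimbabwe males held an implied 20.04% of Zimbabwe RNA. Chance could not be excluded for male line in the mean (2 genes, 7 splits, highest other 9), female line by male line (18 genes, 7 splits, 956), same-line against different-line males (0 genes, 24 splits, 78), or male line in Beijing (2 genes, 22 splits, 32), Netherlands (39 genes, 22 splits, 3797), Tasmania (28 genes, 11 splits, 161) and Zimbabwe females (0 genes, 24 splits, 193).

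Over genes specific to 1 other line, implied shares above 10% were measured in 6 libraries: 55.4% Ithaca in Netherlands x Ithaca replicate 2, 21.1% Zimbabwe in Tasmania virgin replicate 3, 20.04% and 19.9% Zimbabwe in Ithaca x Zimbabwe replicates 3 and 1, 17.1% Beijing in Netherlands x Beijing replicate 2 and 14.2% Zimbabwe in Beijing x Netherlands replicate 2. The measure over genes silent in the female line gave another set, so shares and libraries are uncertain: it had totals above 10% also in Beijing x Tasmania replicate 1 (22.9%), Beijing x Zimbabwe replicate 1 (20.4%), Ithaca x Ithaca replicate 3 (11.6%) and Beijing virgin replicate 1 (10.6%), but 8.94% in Tasmania virgin replicate 3, and 52.6% in Ithaca x Zimbabwe replicate 1.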
